A study of Caenorhabditis elegans with 2 samples.

How the data were processed

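Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans young adults of 1 transgenic strain, OP606. Per the labels, the strain carries an integrated transgene (wgIs606) for F52B5.7 with GFP and FLAG at its C terminus, in an unc-119 mutant background. The tagged protein was pulled down with an antibody against GFP from sonicated chromatin, 63 h after synchronisation as starved L1 larvae. The labels give 2 biological replicates, which form 1 group. A control experiment is named in the labels and was not analysed here.

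The lists were made by the authors on the ce10 and ce11 genome builds. Per the submitters' file manifests, the candidate list of each replicate came from the alignments of that replicate and the control. A pooled candidate list came from both replicates and the control. The optimal list held regions kept after lists were compared by the irreproducible discovery rate (IDR). This rate weighs how well the ranks of regions match between the lists compared. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The score of each region is the signal value in the lists the authors deposited, with no stated scale. It was used to rank and describe regions within a list. A −log10 q value per region, also deposited by the authors, reached the ceiling of 2.98 in 476 regions of the ce11 pooled list and was not used for ranking. Read depth per library is unknown from these lists, and signal tracks were not used here. Each candidate list held 30000 regions, so its length says nothing about depth.

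Regions were annotated on ce11 alone, with Ensembl release 115 gene models and the RefSeq sequence of the same assembly. No coordinates were converted, and the ce10 lists entered only comparisons of counts, overlap between ce10 lists, and matching by signal. A promoter window ran from 1000 bp upstream to 500 bp downstream of an annotated protein-coding transcription start site (TSS). Summits were placed 10000 times at random positions on their own chromosome for a two-sided permutation test, whose smallest possible p is 0.0002. Chromosome shares were compared with the shares of TSSs by two-sided exact binomial tests. Gene lists, 30 in number, were compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Noncoding RNA genes counted as bound when an optimal summit lay in the gene or within 250 bp of it. Each class was compared with protein-coding genes that had a summit within 250 bp of a TSS. The noncoding window thus also spans the gene body, which the protein-coding window does not. All 2080 6-mers, counted on both strands, were compared between 101 bp windows on optimal summits and as many windows on other pooled candidates, matched by GC decile and promoter class. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only. Regions and genes are not biological replicates, and neighbouring genes can share a peak, so p-values describe these lists and not the spread between animals.

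The gene lists, the main tests, most alternatives and the naming rule were fixed before the data were examined. Named were the protein-coding gene with the nearest TSS within 1000 bp of each of the 25 strongest optimal peaks, F52B5.7 and unc-119, and up to 4 members with the strongest peak of each enriched list. The 5 strongest optimal peaks with no protein-coding TSS within 1000 bp and the 5 enriched 6-mers with the smallest p that did not overlap by 5 bases were also named. Other genes are named where a count of 5 or fewer called for it, where genes shared a peak, or where a peak lay nearer to them or in the 40 kb around F52B5.7. Classes of peaks, tests of each chromosome, gene parts at summits, tRNA isotypes, spliced leader genes, the 40 kb windows, the alternatives without peaks near noncoding RNA genes or around F52B5.7, the second background draw, the ce10 peak count, chromosome shares against pooled candidates and the match of ce10 with ce11 regions (same chromosome, width and summit offset, signal within 0.1%) were added after the data were seen.

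Alternatives used the 1032 strongest regions of a single replicate, the 516 strongest optimal peaks, other windows, other backgrounds and other overlap criteria. The 8 alternatives counted for each gene list leave out the one without peaks around F52B5.7, which removed 10 peaks. The tests were tested on simulated data. With 25% of ribosomal protein genes and 3% of the other genes bound among 19973 genes, the ribosomal protein list was called in 100 of 100 runs, and 6 of 2900 tests of unchanged lists were called. A 6-mer planted in 10% of windows ranked first in 10 of 10 runs, and 0 6-mers were called without planting. Simulated genes were bound independently, whereas 102 optimal peaks served more than 1 gene. Simulated windows were not matched by GC content or promoter class. These runs therefore do not cover shared peaks or the matching. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.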

Results

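Binding of GFP-tagged F52B5.7 was mapped by ChIP-seq in whole young adult C. elegans in 2 biological replicates of 1 strain. The ce11 optimal list held 1032 peaks with a median width of 390 bp. They were the 1032 strongest regions of the pooled candidate list. Signal values, which are the authors' own, ranged from 115 to 2954 with a median of 147. With a single group, the comparisons are between the replicates, between peaks and genomic background, and between classes of genes.

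The replicates shared part of their strongest regions. Of the 1032 strongest regions of replicate 1, 516 overlapped the 1032 strongest of replicate 2 by at least 1 bp (50%, 95% exact interval 46.9 to 53.1), against 4.28% for random draws of replicate 2 candidates. The share was 64% for the 25 strongest regions of each and 51% for the 100 strongest, lists cut short at the same rank. Of the 25 strongest optimal peaks, 25 overlapped the 1032 strongest regions of both replicates. The same held for 99 of the 100 strongest and 82.6% of the strongest 516. Such overlap is partly built in, because the optimal peaks come from the same 2 libraries. Of the 1032 optimal summits, 492 lay in the 1032 strongest regions of both replicates (47.7%, 44.6 to 50.8) and 78 in those of neither. The optimal peaks were the strongest regions of the pooled list, and some had no candidate in 1 of the replicates. Across the 998 optimal peaks with a candidate in both replicates, Spearman's rho of signal was 0.305, a value across regions that are not independent replicates. The peaks were chosen by pooled signal from both replicates, so this rho does not measure agreement over all candidates.

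**Figure D1:**
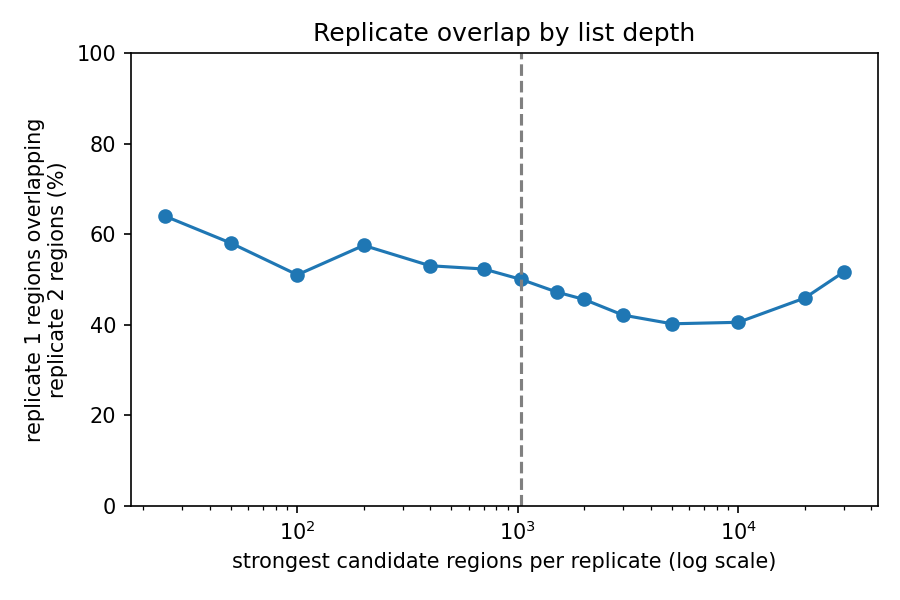
Share of the strongest replicate 1 regions (%, y axis) that overlap equally many strongest replicate 2 regions (x axis, log scale) on ce11; each point is 1 list length and the dashed line marks 1032 regions. At that line the share was 50%.

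The strongest peak lay inside snpc-4, which encodes a subunit of the complex that activates small nuclear RNA genes. Its region spanned positions 8962810 to 8963493 of chromosome I (ce11), with the summit at 8963236 in coding sequence, 914 bp downstream of the TSS. The signal was 2954, or 3.80 times that of the second strongest peak, and the region ranked 1 in both replicates. The second strongest peak (signal 777, chromosome V, summit 8500570) lay in an intron of pxn-1, a peroxidasin gene, beside the snoRNA gene ZK994.7. Further peaks without a protein-coding TSS within 1000 bp lay beside the snoRNA gene T03F7.8 in a cutl-18 intron (629, chromosome V, summit 11314214) and beside the snoRNA genes C51F7.3 and C51F7.4 in a frm-7 intron (596, chromosome V, summit 12303631). Another lay beside the snoRNA gene W03C9.9 outside protein-coding genes (588, chromosome II, summit 11960831). The fifth lay in coding sequence where zip-2 and dos-3 adjoin (511, chromosome III, summit 835964).

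Of the 25 strongest peaks, 12 had a protein-coding TSS within 1000 bp. Besides snpc-4, these were at mdt-26, a Mediator subunit gene (signal 629.9, chromosome II, summit 5661782, intron), and rpl-3, a large ribosomal subunit gene (625, chromosome III, summit 3867572, at -282 bp from the TSS). The peak of tasp-1, a threonine aspartase gene, had a signal of 567 and that of ints-8, an Integrator subunit gene, 504. The ints-8 peak also lay within 250 bp of rpr-1, the RNase P RNA gene, a gene noted after its value was seen. Signals were 429.7 at wwp-1, a ubiquitin ligase gene, and 414 at ego-1, an RNA-dependent RNA polymerase gene of the germline. The peak nearest egg-5, which acts in egg activation, had a signal of 390.0 and lay beside the SL2 spliced leader gene sls-2.4. The ribosomal protein genes rpl-15 and rpl-35 had signals of 374 and 372. The peak of C04A11.5 (364) lay beside a tRNA gene and that of F55A11.6 (351) beside the snoRNA gene F55A11.10.

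**Figure D2:**
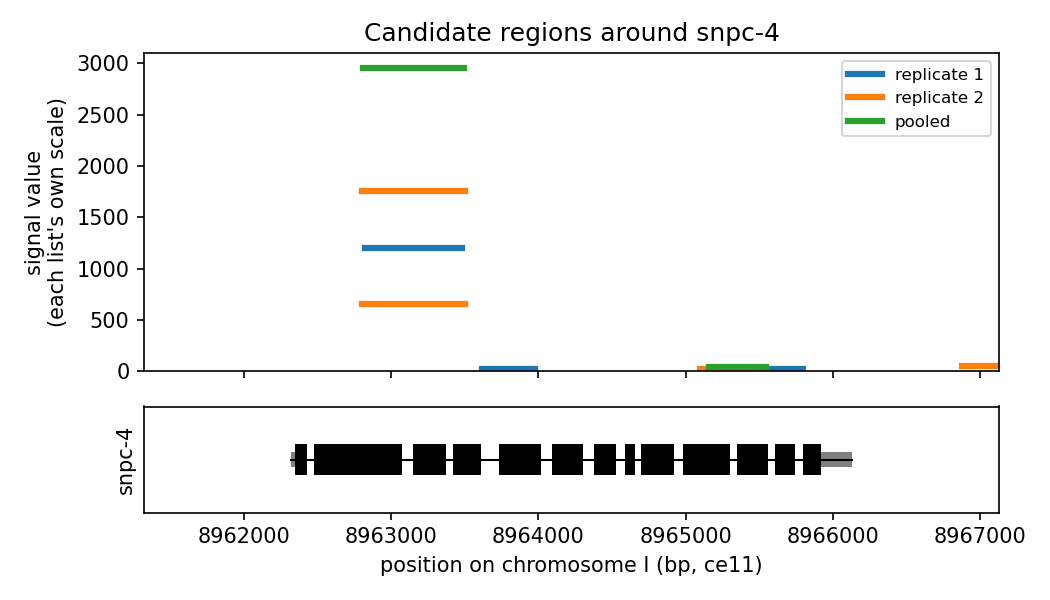
Candidate regions of replicate 1, replicate 2 and the pooled list around snpc-4 on chromosome I (x axis, bp, ce11; y axis, signal value on each list's own scale), with exons in grey and coding sequence in black below. The region with the summit at 8963236 ranked 1 in every list.

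Genes for tRNAs, snoRNAs and snRNAs carried optimal peaks more often than protein-coding TSSs. Of 612 tRNA genes, 183 had an optimal summit within 250 bp of the gene (29.9%, 26.3 to 33.7). Of 19973 protein-coding genes, 267 had one within 250 bp of a TSS (1.34%, adjusted p = 3.15e-164 for the comparison, Fisher's exact test). The snoRNA genes, whose products guide chemical modification of other RNAs, were bound in 64 of 346 cases (18.5%, 14.5 to 23; adjusted exact p = 1.45e-48). Of 129 snRNA genes, 18 were bound (13.95%, 8.48 to 21.2; adjusted exact p = 4.49e-13), counting mir-1831 and sup-39, which are both annotated as snRNA here and share 1 peak. None of 20 annotated rRNA genes had a peak, with an upper limit of 16.8% (adjusted exact p = 1). Many tRNA genes have near-identical copies, so reads there can be hard to place.

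Seen from the peaks, 246 of 1032 (23.8%) lay within 250 bp of a tRNA, snoRNA or snRNA gene, 165 of them near tRNA genes. In classes that count each peak once, snoRNA peaks made up 13.7% of the strongest 344 peaks and 2.62% of the weakest 344 (adjusted p = 5.01e-07, Fisher's exact test over 6 classes). For tRNA peaks the shares were 18.02% and 9.88% (adjusted exact p = 0.00472), with the highest share, 20.06%, in the middle 344.

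**Figure D3:**
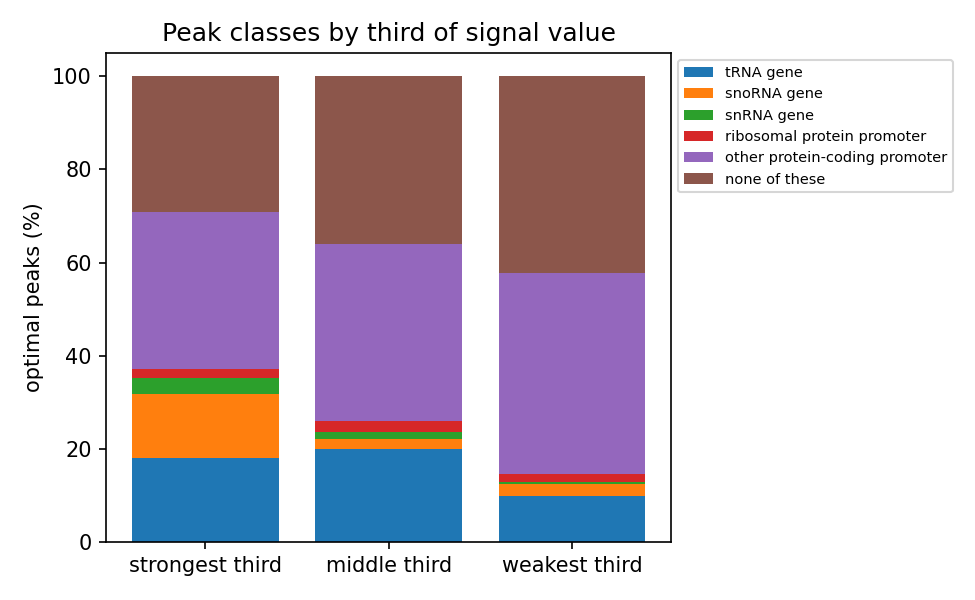
Share of optimal peaks (%, y axis) in 6 classes for the strongest, middle and weakest 344 peaks by signal (x axis); each peak is counted once, in the order of the legend. The snoRNA class takes 13.7% of the strongest and 2.62% of the weakest peaks.

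Peaks lay near protein-coding promoters more often than random positions. Of the 1032 summits, 502 fell in a promoter window (48.6%, 45.6 to 51.7), against 31.6% of random placements on the same chromosomes (permutation p = 0.0002, the smallest possible). The other pooled candidates lay in promoter windows in 34.1% of cases (p = 6.06e-21, Fisher's exact test). Summits lay in coding sequence in 21.4% of cases against 44.6% of 5000 other candidates (adjusted exact p = 7.04e-46), and outside protein-coding genes in 47.4% against 24.3%. The promoter share was 48.3% in the strongest and 50.9% in the weakest 344 peaks (p = 0.542, Fisher's exact test). The sign of this difference turned with only replicate 2 used (4.07 percentage points) and between the stronger and weaker 516 peaks (2.33).

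The promoter windows with a peak belonged to 600 protein-coding genes, 3.004% of 19973. Cytosolic ribosomal protein genes stood out, with 22 of 83 bound (26.5%, 17.4 to 37.3) against 2.91% of other genes (adjusted p = 8.28e-14, Fisher's exact test). Their peaks had a median position of -258.5 bp relative to the TSS, and 15 of the 22 lay upstream. After rpl-3, rpl-15 and rpl-35, the strongest was at rpl-20 (signal 271), nearer to the TSS of Y17G9B.5. In 13 of the 22 genes the peak overlapped the 1032 strongest regions of both replicates. The list also passed the threshold in all 8 alternatives counted, with adjusted exact p from 2.74e-15 to 1.90e-07.

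Smaller excesses were found for 4 other lists. Chromatin regulator genes were bound in 7 of 54 cases (13.0%, adjusted p = 0.0111, Fisher's exact test), led by cbp-1, a histone acetyltransferase gene (signal 315), set-16, a histone methyltransferase gene (206), lin-54 of the DREAM complex (165) and chd-7, a chromatin remodeller gene (146). The lin-54 peak lay at the TSS of rpl-12 and is shared with that ribosomal protein gene, and the set-16 peak lay nearer to the TSS of drr-2. Splicing factor genes were bound in 6 of 50 cases (12%, adjusted exact p = 0.0185), with snrp-200 (257), snr-4 (191), prp-19 (169) and rsp-3 (128) in front. The snr-4 peak lay beside the snRNA gene T11F9.15, and the prp-19 peak nearer to the TSS of K10D2.5. Among the splicing factors, rsp-1 and rsp-2 shared a peak, so the 6 genes rest on fewer peaks. Chaperone genes were bound in 7 of 66 cases (10.6%, adjusted exact p = 0.0185), with dnj-13 (279), hsp-60 (262), hsp-1 (259) and cct-8 (252) strongest, of which the hsp-60 and cct-8 peaks lay nearer to the TSSs of Y22D7AL.10 and Y55F3AR.2. Respiratory chain and ATP synthase genes were bound in 8 of 83 cases (9.64%, adjusted exact p = 0.0185), led by cox-5B (262), cox-6A (239.7), cox-5A (231) and nduf-2.2 (194). The cox-6A peak lay beside the snRNA gene F54D8.7, and the nduf-2.2 peak nearer to the TSS of dlc-1. None of these 4 lists passed when only genes with a pooled candidate served as background (adjusted exact p from 0.245 to 0.259) or when each peak went to its nearest TSS (0.106 to 0.242). Of the 8 alternatives counted, chaperones passed in 6, respiratory chain genes in 4, chromatin regulators in 3 and splicing factors in 2, and the latter 2 lists missed the threshold without replicate 2 (adjusted exact p = 0.203 and 0.0574).

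Chemoreceptor genes, most of which are expressed in few neurons, were depleted, with 3 of 1303 bound (0.230%) against 3.198% of other genes (adjusted p = 4.63e-13, Fisher's exact test). The list passed in all 8 alternatives counted, with odds ratios from 0.0696 to 0.209. Among the 7735 genes with a pooled candidate, 1.52% of its members were bound, an odds ratio of 0.209 against the other such genes (adjusted exact p = 0.00307). Members without a candidate are left out of that share, so it is not to be set against the 3.198%. The 3 bound genes were srh-269, srh-2 and sre-1, named after their values were seen. The srh-269 peak lay beside a tRNA gene, and the srh-2 peak nearer to the TSS of icl-1. C-type lectin and antimicrobial genes were bound in 3 of 350 cases (0.857%, adjusted exact p = 0.0469), namely clec-126, spp-1 and clec-221, but this list passed in only 2 of these 8 alternatives (adjusted p from 0.0369 to 0.298 by Fisher's exact test, the highest without replicate 2). Translation factors missed the threshold (4 of 32, adjusted exact p = 0.0558), as did histones (6 of 83, 0.127) and neuron markers (4 of 44, 0.127). So did the collagen list (9 of 198, 0.360) and muscle markers (1 of 36, adjusted exact p = 1). The collagen list was picked by symbol and not by product, with dpy-11 and dpy-23 among its members. Translation factors passed in 3 of the 8 alternatives, without replicate 1 (adjusted exact p = 0.0132), with 2000 bp upstream (0.01197) and without peaks near noncoding RNA genes (0.0355), and histones passed without replicate 1 (0.0400). Nuclear hormone receptor genes (4 of 273, adjusted exact p = 0.329) also passed without replicate 1, with a lower share than other genes (0.01495). Of the translation factors, ifet-1 shared its peak with the ribosomal protein gene rps-1. Among the histones, his-59 and his-60 shared a peak, as did his-35 and his-41, so the 6 genes rest on fewer peaks. The his-42 peak lay beside the snRNA gene C47F8.9. No peak was found at 40 germline and P granule genes, 39 intestine markers, 31 major sperm protein genes or 30 pharynx and gland markers (adjusted exact p from 0.761 to 1). The other 13 lists had adjusted exact p from 0.201 to 1.

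**Figure D4:**
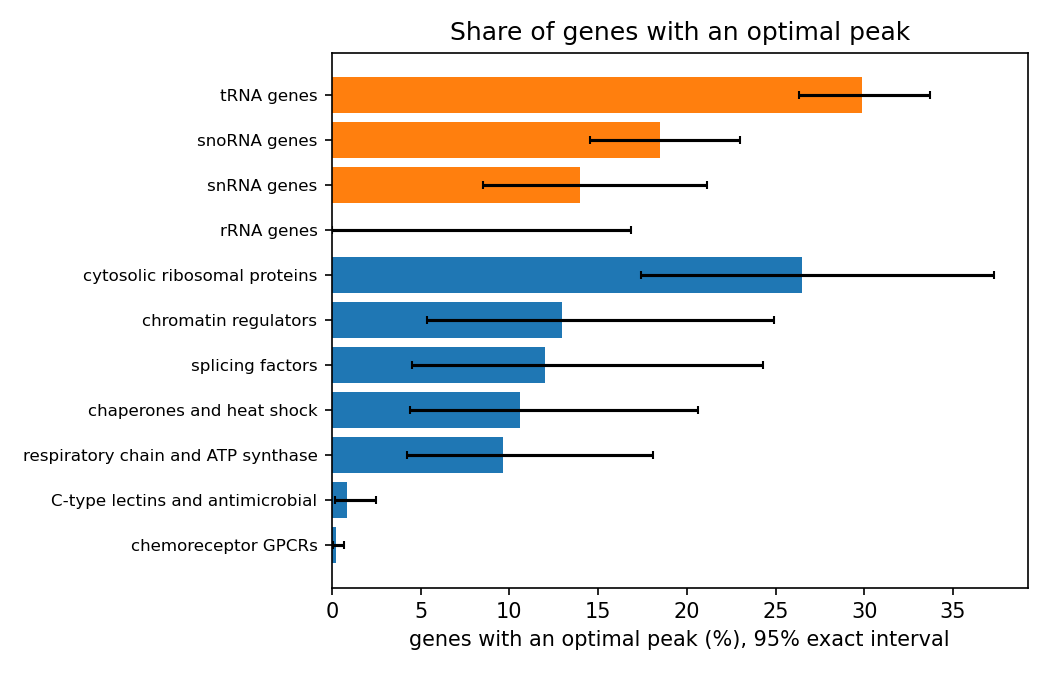
Share of genes with an optimal peak (%, x axis) for 4 classes of noncoding RNA genes (orange, summit within 250 bp) and the 7 gene lists past the threshold (blue, promoter window); error bars are 95% exact intervals for counting error. Shares run from 29.9% for tRNA genes to 0.230% for chemoreceptor genes, with 0 of 20 rRNA genes.

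The X chromosome held 161 optimal peaks (15.6%, 13.4 to 17.96), against 14.04% of protein-coding TSSs (p = 0.152, exact binomial test). Peaks near tRNA genes lay on X in 75 of 165 cases (45.5%), against 45.1% of tRNA genes. The remaining 867 peaks lay on X in 9.92% of cases (8.01 to 12.1; exact p = 0.000348), a split chosen after the data were seen. With tRNA regions included, the 1032 strongest regions of replicate 1 alone lay on X in 17.6% of cases (exact p = 0.00124). Chromosome III held 18.5% of peaks against 13.4% of TSSs (adjusted p = 1.38e-05, exact binomial test over 6 chromosomes) and chromosome V 15.8% against 23.5% (adjusted exact p = 7.33e-09). Pooled candidates lay on III in 16.7% and on V in 19.1% of cases, and against these shares III no longer passed (adjusted exact p = 0.321) while V did (0.0421). On the autosomes, 493 of 871 peaks lay in the central 50% of the chromosome (56.6%), against 56.3% of TSSs (exact p = 0.891).

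At optimal summits, 62 6-mers were enriched over matched candidates at an adjusted p under 0.05 and 34 were depleted. GTTCGA, which occurs in the B box of tRNA gene promoters, was in 12.6% of summit windows against 4.07% of matched windows (adjusted p = 3.09e-09, Fisher's exact test). It was in 41.8% of tRNA windows and 28.6% of snoRNA windows, and in 5.56% of other promoter windows. AGAGCG was in 11.0% against 3.78% (adjusted exact p = 1.62e-07), GAACCC in 8.43% against 3.101% (0.000112), ACCACT in 11.9% against 5.62% (0.000206) and ACGCAG in 10.5% against 4.65% (0.000235). Without tRNA peaks 24 6-mers were enriched, 17 of them among the 62, and of the 5 named here ACGCAG alone still passed (adjusted exact p = 0.0349). Without replicate 1, however, the odds ratio of ACGCAG went from 2.38 to 1.39 and missed the threshold (adjusted exact p = 0.283), and GAACCC missed it in the strongest 516 peaks (0.162) and, with a new background draw, without the peaks around F52B5.7 (0.0677). Another random draw of the background gave 65, of which 40 were shared.

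The ce10 optimal list held 992 peaks, 40 fewer than on ce11. By chromosome it held 172 on I, 164 on II, 181 on III, 163 on IV, 153 on V and 159 on X, against 178, 170, 191, 169, 163 and 161 on ce11. In all, 982 peaks matched between the lists by width, summit offset and signal within 0.1%. Of the 50 ce11 peaks without a match, 39 were weaker than the weakest ce10 peak. The strongest unmatched peak ranked 5 on ce11, the rank of the rpl-3 peak. The weakest signal was 117 in the ce10 list and 115 in the ce11 list.

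No replicate, pooled or optimal region lay within 2000 bp of F52B5.7 (chromosome I, positions 8313121 to 8315432), the gene carried by the transgene. The 40 kb around it nevertheless held 10 optimal peaks, against a median of 0 for such windows, and no window held more. Of these, 5 lay nearest to abts-1, 2 to cep-1, 2 to F52B5.3 and 1 to C34B7.1, with summits from 8301246 to 8331125 and signals up to 231. Without them, an alternative chosen after the data were seen, 598 genes were bound, 48.8% of summits lay in promoter windows and each of the 7 lists still passed. The 6-mer GAACCC did not pass, but that run also used a new background draw, so the 2 changes cannot be told apart. At unc-119, the gene used as a transgenesis marker (chromosome III, 10902641 to 10908935), replicate 2 had 3 candidates, the best at rank 8473, and the other lists had none.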

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

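Alternatives without peaks near tRNA or other noncoding RNA genes or around F52B5.7, with another background draw, and the ce10 peak count and chromosome shares against candidates were chosen after seeing the data. No paired analysis was possible because the series has 1 group. The promoter share stayed above its background in all 8 alternatives, and 3 noncoding classes passed in all 6. Replicate overlap was 43.1% with 50% reciprocal overlap, 44.4% with summits within 100 bp, 53.5% with 516 regions and 45.5% with 2064. Optimal summits found in both replicates reached 77.6% with 2064 regions each and 95.7% with all candidates, a share nearly fixed because the optimal peaks come from the same 2 libraries. The X share, 15.6%, lay below the 17.7% expected by length. It was 15.02% to 17.6% with 1 replicate left out and 18.99% in the strongest 516 peaks (exact p = 0.00185). Without tRNA peaks it was 9.92%, a drop that follows from removing peaks near X-rich tRNA genes. That removal does not show why the remaining share lay below that of TSSs. The central share was 56.1%, below TSSs, without the peaks around F52B5.7, ranged from 55.3%, also below, to 56.9% with 1 replicate left out, and 56.6% exceeded 50% by length and 47.9% of candidates. Chromosome IV, with 16.4% of peaks, lay below its TSS share and above its 14.8% of candidates. The difference in promoter share, strong minus weak peaks, was -2.62 percentage points in the main run. It was 0 to 4.07 with 1 replicate left out and 2.33 between the stronger and weaker 516, so its sign was not stable. The strongest 516 peaks gave 307 genes, 3 lists and 38 6-mers, with fewer peaks tested. Lists past the threshold numbered 4 to 10 with 1 replicate left out, 3 with 500 bp either side of the TSS, 2 with the nearest TSS alone and 2 with candidate genes as background. Enriched 6-mers numbered 51 to 59 with 1 replicate left out, 668 against flanking windows, 140 in wider windows and 24 without tRNA peaks. For the other changes the cause was not tested. Read depth is unknown, which leaves open how far it limits the weaker peaks.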

Other observations

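The comparisons of spliced leader genes and isotypes were chosen after the data were seen, as were the tests of a single library, the snpc-4 interval, snoRNA copies, muscle genes and the X share. Among snRNA genes, the SL2 spliced leader genes, whose RNAs are joined to downstream genes of operons, were bound in 8 of 18 cases (44.4%), against 10 of 111 other snRNA genes (9.01%; p = 0.000572, Fisher's exact test). In the windows of snRNA peaks 16.2% of 36-mers had other genomic copies, so shared reads stay open for these genes. The RNase P RNA gene rpr-1 and the RNase MRP RNA gene mrpr-1 each had a peak within 250 bp, and the Y RNA gene yrn-1 had none. Of 15363 piRNA genes, 15 were near a peak (0.0976%), and of 261 miRNA genes 10 (3.83%). No tRNA isotype of 21 differed from the other tRNA genes (smallest adjusted p = 0.688, Fisher's exact test, for tRNA-Cys with 7 of 13 bound). Bound tRNA genes made up 31.2% of those on X and 28.9% of those on autosomes (p = 0.595, Fisher's exact test).

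The 40 kb around F52B5.7 held 30 pooled candidates, against a median of 11 for such windows, more than 98.7% of them. Replicate 1 had 28 there, replicate 2 had 36 and the optimal list 10. Whether these regions reflect binding or the transgene was not tested, and none lay within 2000 bp of the gene.

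The snpc-4 region exceeded all others in signal. Of its 36-mers, 0% occurred elsewhere in the reference genome, which argues against reads shared with other copies in that reference. Copies missing from the reference cannot be seen this way, so they stay open. Its signal was 2.68 times that of the next region that did not overlap it in replicate 1 and 4.55 times in replicate 2, where a second candidate with a signal of 653 overlapped it; this argues against the signal of a single library. The 40 kb around snpc-4 held no fewer candidates than 85.5% of windows in replicate 1, 75.03% in replicate 2 and 65.0% in the pooled list, against extra copies of an interval, but its 2 optimal peaks, the snpc-4 peak among them, were no fewer than in 97.8% of windows, so this stays open. A short contaminating DNA fragment was not tested, and no biological explanation was tested.

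The frequent peaks at tRNA and snoRNA genes were weighed against composition and copies. Matched for GC content and promoter class, other candidates lay near these genes in 1.26% of cases against 22.1% of peaks (p = 2.05e-57, Fisher's exact test), which argues against GC content as the whole cause. Of the 36-mers at snoRNA peaks 0.746% had other copies, against shared reads there, but at tRNA peaks 32.4% had, so shared reads stay open for tRNA genes. Signal at strongly transcribed genes whatever the tagged protein cannot be told apart from binding without a control group: muscle genes were bound in 2.78% of cases against 26.5% of ribosomal protein genes (p = 0.00192, Fisher's exact test), but their transcription was not measured. No biological explanation was tested.

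Away from tRNA genes, X held few peaks. Other candidates away from tRNA genes lay on X in 14.5% of cases, against 9.92% of such peaks (p = 9.85e-05, Fisher's exact test). This argues against a shortage of candidate regions on X. These candidates are weaker than the optimal peaks, so whether strong peaks can be called as readily on X stays open. The share away from tRNA genes was not checked in single replicates. No biological explanation was tested.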
